A study of Saccharomyces cerevisiae with 164 samples.

How the data were processed

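Expression was measured by the authors as counts per gene in 164 libraries of yeast strains with engineered H3 plasmids. The deposited values are raw counts, 1 file per library, with no normalization. Per the labels, 98 libraries of batches 1 to 9 are dUTP strand-specific poly(A)+ RNA-seq, and 66 libraries of batches 10 and 11 are 3′-end RNA-seq, made by oligo-dT priming with a barcode, pooling and tagmentation, with no molecular identifiers named. The submitters' processing notes name TopHat2 2.0.12 with Bowtie2 and the build sacCer3. Per the file headers, full-length fragments were counted as pairs on the reverse strand over 6692 gene features with reads marked as duplicates ignored. The 3′-end reads were aligned with a tool whose path names bwa and counted on the same strand over 5013 transcript features with duplicates kept. Both used featureCounts at a minimum mapping quality of 30.

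Gene names and coordinates were taken from the R64 reference by systematic name. All 5013 of the 3′-end features and 6008 of the 6692 full-length features matched a gene there, and 6000 of the latter had the same coordinates. The 3′-end features are transcripts with other ends than the reference genes, so the printed coordinates are those of the reference genes. Samples were grouped by mutant and by form (H3X, H3Y, symmetric or pseudo-wild-type) as labelled, and the batch was taken from the labels. The file names carry strain numbers. Those of full-length K18Q H3X replicate 2 and K37Q H3X and H3Y replicate 2 differ from the rest of their groups. They may be other isolates and were kept as labelled. Whether the replicate numbers pair the 3′-end libraries was checked from the correlation, across genes, of deviations from the strain means. In K56R H3X and H3Y all 3 same-number pairs had r above 0.1 (0.14 to 0.43). The labels name no pairing, the reported fit of this comparison is unpaired, and a fit with the number as a block is given as an alternative. K36Q double and H3X had 0.12 to 0.32, but no comparison is made of that pair alone. Of 18 strain pairs these 2 had all 3 above 0.1 and 2 had all 3 below -0.1.

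Tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-tests, TMM normalization, filterByExpr on the groups), with p-values adjusted by Benjamini-Hochberg within each comparison and a threshold of 0.05. For the 3′-end data each batch of 33 libraries was fitted on its own, with 4984 genes tested in batch 10 and 4961 in batch 11 (23 residual degrees of freedom, biological coefficient of variation 0.110 and 0.132). For the full-length data all 98 libraries were fitted with the sequencing batch as a term (6376 genes, 35 residual degrees of freedom, coefficient of variation 0.207). Of the 9 batches, 5 hold no pseudo-wild-type library and, except batch 9, share strains with others. Strains with 1 library are assumed to vary like the others. For each of the 3′-end mutants, 4 comparisons were made: symmetric against pseudo-wild-type, the mean of H3X and H3Y against pseudo-wild-type, symmetric against that mean, and H3X against H3Y. That made 24, and 25 full-length comparisons were added, in which full-length K14R, K18R and K56R appear only where named. CPM values are TMM-normalised, except those of the deleted and plasmid histone genes by which genotypes were checked and those of single pseudo-wild-type libraries that stood apart, which are plain CPM.

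The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. Genes were named by a rule set then: they carry a standard symbol and a mean of at least 5 CPM. For symmetric 3′-end strains the rule takes the 6 largest rises and 6 largest falls past the threshold with all 3 mutant libraries beyond all 6 pseudo-wild-type libraries (chance gives 2.38%), for other comparisons the 3 largest each way, and for each list passing the set test up to 4 members with the smallest p. Histone genes and plasmid markers are always listed. The 30 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists and mutants within each family of comparisons, and list results are given with the adjusted p from an estimated correlation because 0 lists passed with it in any of the 8 families. A list was tested from 5 members upward, and a list's median is that of its members' log2 fold changes.

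The ratio of asymmetric to symmetric effects used the 200 genes with the smallest p in the full-length symmetric comparison, signs taken there, and the mean log2 changes in the 3′-end data, with a ratio given only where the symmetric mean exceeds 2 jackknife standard errors. Chromosome segments were searched for as runs of 15 or more windows of 25 genes with a median log2 ratio to the batch median beyond 0.45, after removal of trends on coding length and base content, in genes above a mean of 20 CPM. This search covered 157 libraries, and 7 with a spread above 0.45 were not searched. Alternatives planned at the start were DESeq2 1.42.0, RLE size factors, no filter on low counts, fits of the mutant and pseudo-wild-type alone, a joint fit of both assays over 5011 features, a replicate block, other numbers of genes for the ratio, and leaving out each library in turn. Others were added after seeing the data: each library's slopes of log2 CPM on coding length and on A content as covariates, and leaving out the shallowest libraries, the libraries with the largest spread or the genes in raised segments, summing pseudo-wild-type replicates 1, 2 and 3, and the slopes together with the replicate block in K56R H3X against H3Y. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.

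The edgeR test was tested on simulated counts drawn gene by gene, with 200 changed genes and no trend on coding length between libraries. With 3 libraries against 6 of the K56R design it recovered 65.7% of 1.5-fold, 97.0% of 2-fold and 100% of 3-fold changes, and in the full-length K9R design 7.46%, 22.4% and 65.2%. Segment search, camera and the ratio were likewise tested on simulated data. Total counts per library range from 750551 to 5156160 in the 3′-end and from 542727 to 21573351 in the full-length data. Gene counts cannot show the H3 substitutions themselves, which were taken from the labels. No counts of called genes are given for the full-length R2K, K36Q and K37Q strains, whose libraries entered the full-length and joint fits, the ratio, the comparison of assays and the segment search.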

Results

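RNA was measured in 164 libraries of Saccharomyces cerevisiae grown in rich glucose medium to mid-log phase. The strains lack both chromosomal H3-H4 gene pairs and live on a pair of centromeric plasmids, one marked with TRP1 and the other with LEU2. Each plasmid carries an H3 variant built to pair with the other and not with itself, here called H3X and H3Y as in the labels. A substitution in H3X or in H3Y alone gives nucleosomes with a single changed H3 (asymmetric strains), a substitution in both gives symmetric strains, and the pseudo-wild-type carries neither. There were 21 mutants, 13 in both forms and 8 in the asymmetric form alone. The 3′-end libraries numbered 66 in 19 groups. Batch 10 held R2K, K36Q and K37Q, batch 11 held K14R, K18R and K56R, and each batch held 3 libraries per strain and 6 of the pseudo-wild-type. The 98 full-length libraries of batches 1 to 9 fell into 56 groups, of which 17 had 1 library, 38 had 2, and the pseudo-wild-type had 5. Total counts ran from 750551 to 5156160 per 3′-end library (median 3222807.5) and from 542727 to 21573351 per full-length library (median 5094397).

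In the 3′-end libraries, counts of the H3 genes followed the labelled genotype, while those of the H4 gene HHF1 did not in every strain. Point substitutions cannot be read from gene counts. HHT1, a deleted H3 gene, had 0 counts in 65 of 66 3′-end libraries and at most 0.242 CPM (counts scaled to library size), and HHF1 had 0 in all 66, although the labels place an HHF1 gene on some of the plasmids. Whether those plasmids carry HHF2 instead, or reads of HHF1 were lost because they map to both H4 genes, was not tested. HHT2, whose coding sequence is on both plasmids, ranged from 2806 to 6481 CPM over the 3′-end libraries. In the full-length libraries some counts fell on the deleted genes, with a median of 1.53 CPM and up to 32.1 CPM (K18Q H3X replicate 1) for HHT1, and a median of 2.21 CPM and up to 27.96 CPM (K14Q H3Y replicate 1) for HHF1. Pseudo-wild-type full-length replicates 1, 2 and 3 were sequenced in batches 2, 3 and 4 and differed from one another by little more than counting error (chi-square per degree of freedom 1.14 to 2.69, against 8.50 to 290 in 45 other pairs of one strain). They were counted as 1 in means and standard deviations (n = 3 pseudo-wild-type samples), and entered the tests as separate libraries. Among 3′-end pairs of one strain, symmetric K56R replicates 3 and 4 differed least (1.59, against 2.42 to 72.4 in the other 83 pairs). The excess of their spread over counting error was a log2 SD of 0.049, against 0 to 0.067 among those pseudo-wild-type replicates and 0.084 or more in the other 3′-end pairs. Whether they come from separate cultures cannot be told, and they are counted as separate here (n = 3 for symmetric K56R), with results for their sum given below.

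K56 lies in the globular core of H3, close to where DNA enters the nucleosome, and is acetylated on newly made H3. Arginine keeps the charge and cannot be acetylated. Here and below, the largest changes are those among genes with a standard symbol and a mean of at least 5 CPM. In symmetric 3′-end strains they are also limited to genes with all 3 mutant libraries beyond all 6 pseudo-wild-type libraries. In the symmetric K56R strain some genes of growth on carbon sources other than glucose rose. CAT8, the activator of gluconeogenesis genes (YMR280C, chromosome XIII, 827028 to 831329 of build R64), was at 27.3 ± 0.364 CPM (SD, n = 3) against 9.37 ± 2.91 CPM (n = 6) in the pseudo-wild-type (log2 fold change 1.52 ± 0.23, the error being the standard error, edgeR adjusted p = 4.36e-05). The hexose transporter gene HXT5 (YHR096C, chromosome VIII, 294669 to 296447) was at 90.6 ± 6.34 against 32.7 ± 4.89 CPM (log2 fold change 1.47 ± 0.13, edgeR adjusted p = 3.35e-08). SIP4, a CAT8 target that itself activates gluconeogenesis genes (YJL089W, chromosome X, 265926 to 268415), was at 22.4 ± 1.17 against 8.10 ± 1.46 CPM (log2 fold change 1.46 ± 0.22, edgeR adjusted p = 5.54e-05). The other genes with the largest rises were RAD26 of transcription-coupled repair (1.42), IRC20, a ubiquitin ligase and helicase gene (1.41), and GYP5 of vesicle traffic (2.65-fold). The largest falls were those of VPH2 of vacuolar proton pump assembly (-1.10), the cell cycle repressor gene YOX1 (-1.07), the cell wall protein gene CWP1 (306 ± 17.6 against 625 ± 91.8 CPM, log2 fold change -1.03), the peroxidase gene GPX2 (-0.92), PSA1, which makes GDP-mannose (-0.90), and the acetyltransferase gene NAT5 (-0.89).

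Among the gene lists fixed before the data were examined, some carbon source and stress genes rose in symmetric K56R, while 0 lists passed with an estimated correlation. Of 31 glucose-repressed and post-diauxic genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone). Their median was 0.34 (adjusted p = 0.316 with an estimated correlation). Of 59 stress-induced genes, 26 rose and 0 fell (27 and 0 adjusted over the list alone). Their median was 0.35 (adjusted p = 0.389 with an estimated correlation). The small heat shock protein gene HSP26 was among them at 350.2 ± 55.1 against 173 ± 30.0 CPM (log2 fold change 1.02), with the vacuolar mannosidase gene AMS1 (0.83) and the proteasome assembly gene TMA17 (0.67). Of 21 DNA damage response genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone). Their median was 0.23 (adjusted p = 0.347 with an estimated correlation). The photolyase gene PHR1 (1.07), RAD54 of recombination (0.52) and the ribonucleotide reductase gene RNR2 (0.46) rose. Of 34 meiotic genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone). Their median was 0.50 (adjusted p = 0.347 with an estimated correlation). They include ZIP1 (1.24) and MSH5 (1.15), both of meiotic recombination. Some glycolytic genes moved the other way, with falls of the enolase gene ENO2 (-0.82), the aldolase gene FBA1 (-0.66), PFK2 (-0.63) and TPI1 (-0.44). Of 27 glycolytic genes, 3 rose and 13 fell (4 and 13 adjusted over the list alone). Their median was -0.23 (adjusted p = 0.347 with an estimated correlation). Of 130 ribosomal protein genes, 0 rose and 80 fell (0 and 96 adjusted over the list alone). Their median was -0.43 (adjusted p = 0.347 with an estimated correlation). Examples are RPL3 (-0.51) and RPS7B (-0.49). Of 9 histone genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone). Their median was -0.28 (adjusted p = 0.347 with an estimated correlation). The falls were in the H2A and H2B genes HTA2 (-0.71) and HTB2 (-0.62), the linker histone gene HHO1 (-0.40) and HTZ1, which encodes H2A.Z (-0.28). Of 19 purine and one-carbon genes, 0 rose and 6 fell (1 and 9 adjusted over the list alone). Their median was -0.20 (adjusted p = 0.347 with an estimated correlation). ADE1 (-0.35) and ADE8 (-0.68) of purine synthesis fell.

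Across all genes of symmetric K56R against the pseudo-wild-type, 665 rose and 525 fell, 1190 in total. The log2 CPM of these libraries changed by 0.077 ± 0.007 (SD, n = 3) per doubling of coding length, against -0.064 ± 0.071 (n = 6) in the pseudo-wild-type of the batch, so that long genes stood higher and short ones, ribosomal protein genes among them, lower. A fit that also carried each library's slopes on coding length and A content, chosen after seeing the data, called 729 genes, of which 467 were among the 1190. In it 17 glucose-repressed genes rose and 0 fell (adjusted p = 0.000404 with an estimated correlation), 34 stress-induced genes rose (adjusted p = 0.111 with an estimated correlation), and 37 ribosomal protein genes fell, 36 of them among the 80 (adjusted p = 0.283 with an estimated correlation). In the joint fit of both assays 506 genes were called. With symmetric replicates 3 and 4 summed as 1 library, a choice made after seeing the data, the count was 744 (374 higher and 370 lower). With the slopes as well it was 613, and the glucose-repressed list had an adjusted p = 0.000597 with an estimated correlation. Of the genes named above, VPH2, NAT5 and HTZ1 no longer passed with the sum (edgeR adjusted p = 0.0864, 0.0617 and 0.0829). Without symmetric K56R replicates 3, 4 or 5 the count was 733, 714 and 546. SIP4, RAD26 and RNR2 lie on the left part of chromosome X, whose genes stood higher by a median log2 ratio of 0.20, 0.17 and 0.23 in symmetric K56R replicates 3, 4 and 5.

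**Figure D1:**
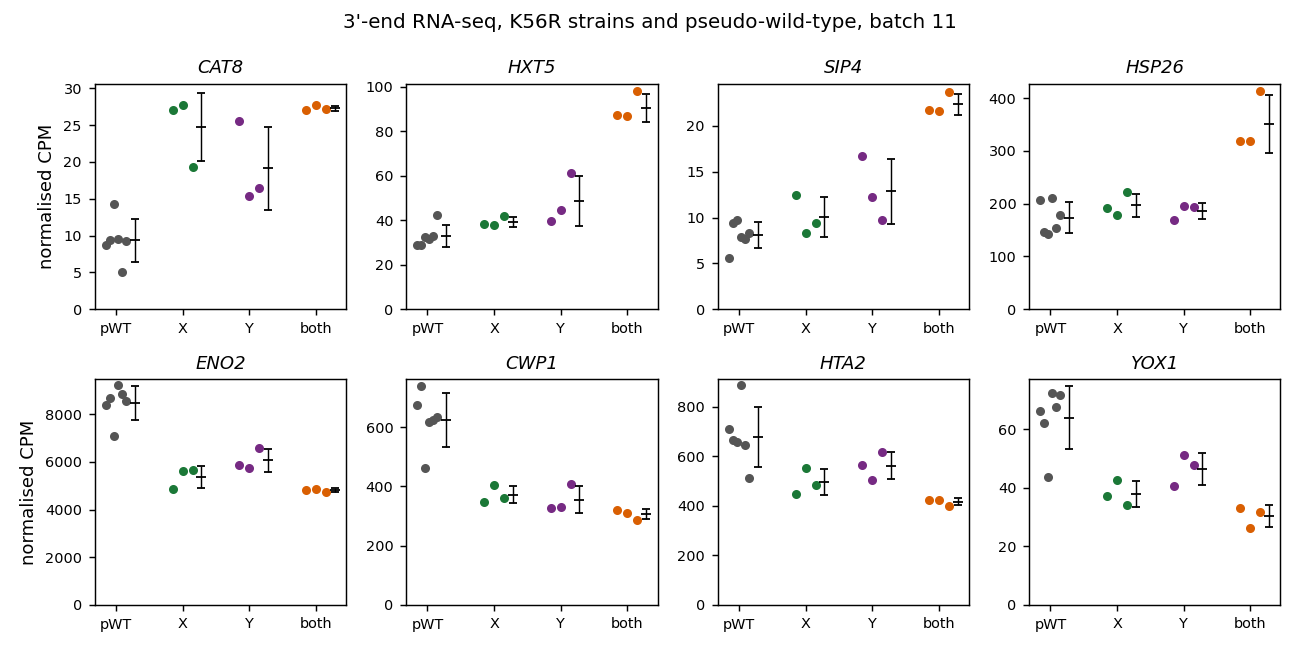
Normalised CPM of genes named for K56R in each 3′-end library of batch 11, for the pseudo-wild-type (pWT), K56R H3X (X), K56R H3Y (Y) and the symmetric strain (both); points are libraries and bars are means. CAT8 stood at a mean of 9.37 CPM in the pseudo-wild-type and 27.3 in the symmetric strain.

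With K56R on 1 of the H3 copies, the question was how far a single changed copy acts. CAT8 rose to 21.9 ± 5.55 against 9.37 ± 2.91 CPM (log2 fold change 1.19 ± 0.20, edgeR adjusted p = 0.000193). POL4, a DNA repair polymerase gene (1.42, chromosome III), and the cohesin gene SMC3 (1.28) had the largest rises with CAT8. The largest falls were those of the ammonium transporter gene ATO3 (-0.79), CWP1 (-0.78) and the aldehyde dehydrogenase gene ALD6 (-0.73). Of 31 glucose-repressed genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). Their median was 0.25 (adjusted p = 0.436 with an estimated correlation). PUT1 of proline use (0.52) and FAA2 of fatty acid activation (0.59) rose. Of 34 meiotic genes, 12 rose and 0 fell (16 and 0 adjusted over the list alone). Their median was 0.47 (adjusted p = 0.419 with an estimated correlation). ZIP1 (1.07) and MSH5 (0.94) rose again. Of 130 ribosomal protein genes, 1 rose and 54 fell (1 and 67 adjusted over the list alone). Their median was -0.27 (adjusted p = 0.436 with an estimated correlation). Of 27 glycolytic genes, 1 rose and 12 fell (3 and 13 adjusted over the list alone). Their median was -0.19 (adjusted p = 0.435 with an estimated correlation). Of 32 chaperone genes, 1 rose and 15 fell (3 and 16 adjusted over the list alone). Their median was -0.26 (adjusted p = 0.435 with an estimated correlation). Examples of these falls are RPL3 (-0.37), ENO2 (-0.57), FBA1 (-0.43), SSA2 (-0.62) and STI1 (-0.58). In total 635 genes rose and 506 fell (1141). Of the 120 tested genes on chromosome III, which stood higher in the H3X strain, 82 were called, all higher (two-sided Fisher's exact test against the rest of the genome, p = 1.23e-26), and outside it 553 rose and 506 fell. Chromosome III was picked out in these same libraries and its genes are not independent, so that p-value describes the calls and is no independent support. With the library slopes 370 were called, 248 of them shared, and in the joint fit of both assays 213. The count was 736, 703 and 696 without H3X replicate 3, H3Y replicate 4 or H3Y replicate 3. With the slopes 10 members of the glucose-repressed list rose (adjusted p = 0.0121 with an estimated correlation).

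Set directly against the asymmetric strains, the symmetric K56R strain had HXT5 at 90.6 ± 6.34 against 43.9 ± 8.80 CPM (log2 fold change 1.05 ± 0.13, edgeR adjusted p = 1.91e-05). FMP16, a mitochondrial stress-response gene (1.08), APS3 of vesicle traffic (1.24, chromosome X) and SIP4 (0.97, chromosome X) were higher as well. The genes with the largest falls were SSP1 of sporulation (-0.85), and RAD18 of damage tolerance (-0.82) and RIM1 of mitochondrial DNA replication (-0.77), both on chromosome III. Of 59 stress-induced genes, 15 rose and 0 fell (30 and 0 adjusted over the list alone). Their median was 0.38 (adjusted p = 0.341 with an estimated correlation). Of 32 chaperone genes, 4 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 0.19 (adjusted p = 0.466 with an estimated correlation). Of 31 glucose-repressed genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.17 (adjusted p = 0.466 with an estimated correlation). Examples are HSP26 (0.87), TFS1, a protease inhibitor gene (0.81), TMA17 (0.54), HSP82 (0.61) and PUT1 (0.56). Over all genes 60 rose and 49 fell, 109 in total. Of these 43 lie on chromosome III, which stood higher in the H3X strain, and all 43 are lower. Outside it 60 were higher and 6 lower. Of the 42 called outside every raised segment, chromosome X included, 25 still pass when p is adjusted without the segment genes. The interval of chromosome X with APS3 and SIP4 stood higher by a median log2 ratio of 0.17 to 0.23 in the symmetric libraries. Without symmetric replicates 3, 4 or 5 the count was 49, 43 and 38. With replicates 3 and 4 summed it was 47 (21 higher and 26 lower), and APS3 no longer passed (edgeR adjusted p = 0.0674). A fit with the library slopes gave 339 (198 higher and 141 lower), the 109 among them, and 214 with that sum as well.

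Whether it matters which engineered copy carries the substitution was asked by comparing H3X with H3Y. In K56R, 108 genes were higher and 39 lower in H3X (147), and 126 were called with the replicate number as a block. On chromosome III, from 15798 to 314981, 99 of 120 tested genes were called, all higher, with a median log2 fold change of 0.89 (two-sided Fisher's exact test against the rest of the genome, p = 5.85e-148). This p-value is no independent support, since these same libraries picked out the chromosome and its genes are not independent. MRC1 of the replication checkpoint (YCL061C, chromosome III, 18816 to 22106, log2 fold change 1.32 ± 0.30), the membrane heat shock gene HSP30 (1.27) and POL4 (1.27) had the largest rises and lie there. Off chromosome III, 9 genes were higher and 39 lower. Of the 43 outside every raised segment, only 13 still pass when p is adjusted without the segment genes, and SHM2 is not among them. The lower ones include the a-factor gene MFA1 at 17.2 ± 7.18 against 37.5 ± 4.45 CPM (log2 fold change -1.14 ± 0.22, edgeR adjusted p = 0.00111), the alpha-factor receptor gene STE2 (-0.73), ATO3 (-1.03), the biotin transporter gene VHT1 (-0.64) and SHM2 of one-carbon metabolism (-0.49). Of 22 mating genes, 2 rose and 6 fell (2 and 8 adjusted over the list alone). Their median was -0.38 (adjusted p = 0.971 with an estimated correlation). Those that rose were FIG2 (0.77) and KAR4 on chromosome III (0.76). All 5 K56R H3X libraries, 2 of them full-length, had chromosome III at a median log2 ratio of 0.84 to 0.91 to the median library of their batch, and the 6 H3Y and symmetric 3′-end libraries were between -0.068 and 0.017.

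**Figure D2:**
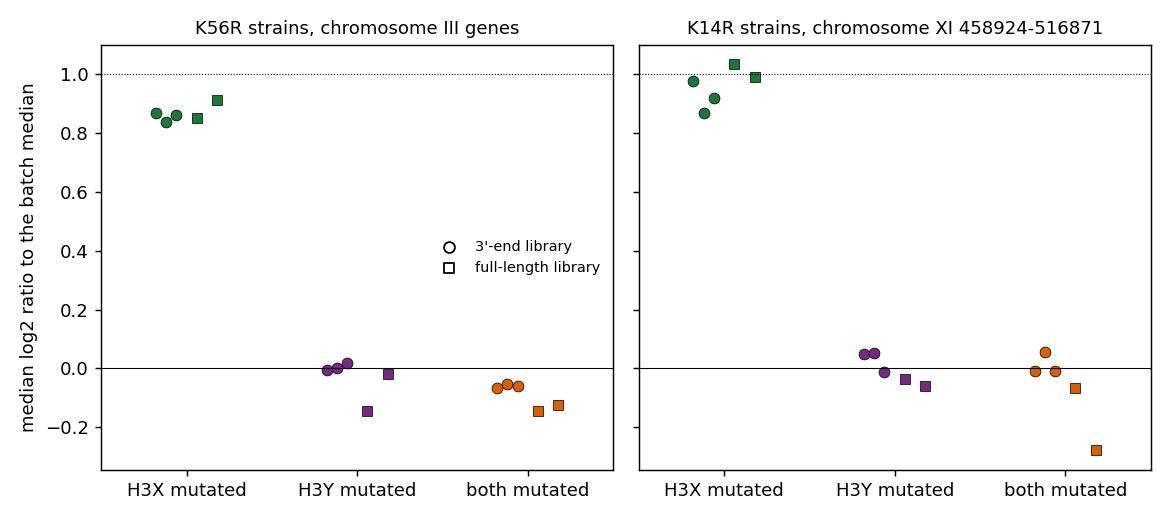
Median log2 ratio to the batch median of genes on chromosome III in K56R libraries and on the chromosome XI segment in K14R libraries, for H3X, H3Y and symmetric strains; each point is a library (circles 3′-end, squares full-length). The 5 K56R H3X libraries sit at 0.84 to 0.91 and the 5 K14R H3X libraries at 0.87 to 1.03.

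K14 is a major acetylation site of the H3 tail. In symmetric K14R, MLP1 of the nuclear pore (YKR095W, chromosome XI, 619805 to 625432) was at 197 ± 40.1 against 47.7 ± 34.4 CPM (log2 fold change 2.02 ± 0.43, edgeR adjusted p = 0.00119). The vesicle tether gene USO1 (1.89), UTP14 (1.75) and SAS10 (1.71) of ribosome assembly, MLP2 (1.72) and ZIP1 (1.67) followed. GDH1, which assimilates ammonium, fell (115 ± 6.65 against 227 ± 23.3 CPM, log2 fold change -0.97 ± 0.10, edgeR adjusted p = 2.16e-07), as did the agglutinin gene AGA2 (-1.09), the a-factor barrier gene AFB1 (-1.03), BIO2 of biotin synthesis (-1.01), INA17 (-1.20), TAH1 (-1.09) and YOP1 (-0.98). Of 75 ribosome biogenesis genes, 50 rose and 1 fell (54 and 1 adjusted over the list alone). Their median was 0.49 (adjusted p = 0.389 with an estimated correlation). UTP7 was among the rises (0.83). Of 31 chromatin genes, 12 rose and 1 fell (13 and 2 adjusted over the list alone). Their median was 0.20 (adjusted p = 0.316 with an estimated correlation). They include the silencing genes SIR3 (1.20) and SIR4 (1.14) and the SAGA and NuA3 genes SPT7 (1.25) and SAS3 (1.11). Of 130 ribosomal protein genes, 0 rose and 84 fell (0 and 93 adjusted over the list alone). Their median was -0.41 (adjusted p = 0.389 with an estimated correlation). Of 59 amino acid synthesis genes, 1 rose and 28 fell (1 and 30 adjusted over the list alone). Their median was -0.26 (adjusted p = 0.347 with an estimated correlation). Of 59 stress-induced genes, 2 rose and 19 fell (2 and 19 adjusted over the list alone). Their median was -0.26 (adjusted p = 0.447 with an estimated correlation). Among these falls were RPL23A (-0.63), RPS2 (-0.61), GCY1 (-0.91) and YGP1 (-0.74). Over all genes 1012 rose and 789 fell (1801), and 1115 were called without symmetric replicate 5.

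The slope of log2 CPM on coding length was 0.112 ± 0.016 (SD, n = 3) per doubling in the symmetric K14R libraries, against -0.064 ± 0.071 (n = 6) in the pseudo-wild-type. In the joint fit of both assays 358 genes were called. With the library slopes in the fit 42 genes were called, 27 of them among the 1801, MLP1 had a log2 fold change of -0.059 and UTP14 of -0.12, and 0 ribosome biogenesis and 0 ribosomal protein genes passed. With K14R on 1 copy, MLP1 (1.60), USO1 (1.57) and the histone deacetylase gene SET3 (1.55, inside the chromosome XI segment) had the largest rises, and VPS73 (-0.93), TAH1 (-0.87) and YOX1 (-0.73) the largest falls. Of 75 ribosome biogenesis genes, 54 rose and 0 fell (58 and 0 adjusted over the list alone). Their median was 0.42 (adjusted p = 0.435 with an estimated correlation). Of 130 ribosomal protein genes, 0 rose and 36 fell (0 and 40 adjusted over the list alone). Their median was -0.23 (adjusted p = 0.528 with an estimated correlation). There were 865 rises and 583 falls (1448, and 18 in the joint fit of both assays), with 22 of the 26 tested genes of the chromosome XI segment, raised in the H3X strain, among the rises. The count was 909 without H3X replicate 3, and 9 genes with the library slopes, where MLP1 was at -0.041. Between the symmetric and the asymmetric K14R strains, 0 genes rose and 2 fell, GCN3 of translation control (-0.55) and PRY2 of sterol export (-0.54), both in the chromosome XI segment, and DESeq2 called 21. The joint fit of both assays called 266, with PRY2 at 0.019, and the fit with the library slopes called 47.

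In K14R H3X against H3Y, 22 genes were higher and 1 lower. Of the 26 tested genes on chromosome XI from 458924 to 516871, 17 were called, all higher (median log2 fold change 0.90, two-sided Fisher's exact test p = 1.71e-37). Here too the segment was found in the same libraries, so the p-value only describes the calls. BCH2 of secretory cargo export (YKR027W, chromosome XI, 491364 to 493661, log2 fold change 1.29 ± 0.20, edgeR adjusted p = 0.000187), VPS51 of vesicle tethering (1.21) and PRY2 (1.18) had the largest rises, and the spindle pole gene SPC72 was lower (-0.99). All 5 K14R H3X libraries had this segment at 0.87 to 1.03.

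**Figure D3:**
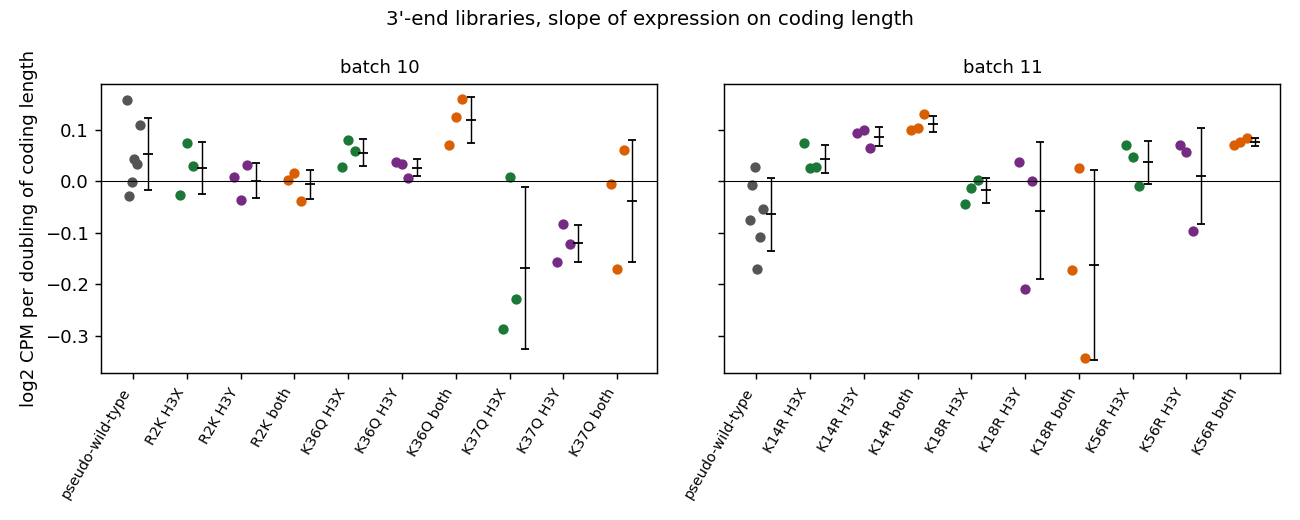
Slope of log2 CPM on log2 coding length for each 3′-end library, by strain, in batches 10 and 11 (points are libraries, both marks the symmetric strains). The symmetric K14R libraries averaged 0.112 and the pseudo-wild-type of batch 11 averaged -0.064, with a range of -0.170 to 0.027.

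K18 is another acetylated lysine of the H3 tail. In symmetric K18R some stress-induced genes fell, in calls that were lost when K18R double replicate 5 was left out. The amino acid permease gene DIP5 (YPL265W, chromosome XVI, 41043 to 42869) was at 50.2 ± 6.75 against 112 ± 37.9 CPM (log2 fold change -1.14 ± 0.26, edgeR adjusted p = 0.0194). The other largest falls were those of TSL1 of trehalose synthesis (-0.92), RTC3 (-0.84), the chaperone gene HSP42 (-0.80), GPD1 of glycerol synthesis (-0.76) and PNC1 of NAD salvage (-0.75). Of 59 stress-induced genes, 0 rose and 11 fell (2 and 26 adjusted over the list alone). Their median was -0.33 (adjusted p = 0.316 with an estimated correlation). GLC3 of glycogen branching (-0.73), GCY1 (-0.69) and YGP1 (-0.55) are examples. Of 32 chaperone genes, 0 rose and 3 fell (1 and 11 adjusted over the list alone). Their median was -0.19 (adjusted p = 0.316 with an estimated correlation). SIS1 (-0.54) and HSP82 (-0.53) fell. Among genes whose mutant libraries all lie beyond the pseudo-wild-type, the largest rises were those of the kinetochore gene DAD3 (0.95), DPA10 (0.88), EMP46 of secretion (0.88), BNA4 of NAD synthesis (0.86), HHT2 itself (7607 ± 2348 against 4377 ± 445 CPM, log2 fold change 0.80) and BET3 (0.78). Of 130 ribosomal protein genes, 11 rose and 0 fell (28 and 2 adjusted over the list alone). Their median was 0.13 (adjusted p = 0.761 with an estimated correlation). RPL41B (1.77), RPS31 (1.82) and RPL23B (1.82) rose, but RPS31 and RPL23B stood at -0.068 and -0.058 once K18R double replicate 5, the shallowest library of the batch, was left out. Over all genes 65 rose and 29 fell (94, with 244 by DESeq2 and 40 in the joint fit of both assays). Only 6 rose and 20 fell with the library slopes, and of the rises named only HHT2 and BNA4 passed. Past a 2-fold change 42 were higher. The count was 0 without double replicate 5, 588 without double replicate 4, and 54, 43, 46 and 40 without pseudo-wild-type replicates 14, 15, 18 and 19. With K18R on 1 copy edgeR called 0 genes (473 at an unadjusted p under 0.05, 0 by DESeq2, and 9 without pseudo-wild-type replicate 16), between the forms 0 (577, and 110 by DESeq2, with 531, 86 and 120 without double replicates 4 and 3 and H3Y replicate 4), and between H3X and H3Y 0 (92, and 0 by DESeq2).

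Glutamine at K37 resembles an acetylated lysine. In symmetric K37Q, BNA1 of NAD synthesis (YJR025C, chromosome X, 471138 to 471671) was at 31.2 ± 3.35 against 17.3 ± 3.66 CPM (log2 fold change 0.84 ± 0.18, edgeR adjusted p = 0.0371). MOG1 of nuclear import (0.65) and the acetyl-CoA synthetase gene ACS1 (0.62) rose, and EDC3 of mRNA decay (-0.81) and the copper transporter gene CTR1 (-0.51) fell. The total was 6, with 4 up and 2 down, and 9 by DESeq2, but 0 with the library slopes and 0 with only the mutant and the pseudo-wild-type in the fit, so that none of these genes passed there. It includes YIR018C-A, named after its values were seen. Of 8 galactose genes, 0 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was 0.36 (adjusted p = 0.316 with an estimated correlation). Of 131 ribosomal protein genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was 0.21 (adjusted p = 0.5 with an estimated correlation). Of 75 ribosome biogenesis genes, 0 rose and 0 fell (0 and 20 adjusted over the list alone). Their median was -0.30 (adjusted p = 0.389 with an estimated correlation). The count was 104 without pseudo-wild-type replicate 10, 3 without replicate 9, 1 without replicate 8, 0 without replicates 11, 12 or 13, 0 without K37Q double replicate 4 and 1 without double replicate 5. With the substitution on 1 copy, TMA19 of translation (1.19), RPS31 (1.16) and SPT4 of transcript elongation (1.15) had the largest rises, and USO1 (34.0 ± 21.8 against 132 ± 55.0 CPM, log2 fold change -1.85 ± 0.38), MLP1 (-1.75) and MLP2 (-1.71) the largest falls. In these strains, of 131 ribosomal protein genes, 96 rose and 0 fell (99 and 0 adjusted over the list alone). Their median was 0.43 (adjusted p = 0.435 with an estimated correlation). Of 27 glycolytic genes, 14 rose and 1 fell (15 and 2 adjusted over the list alone). Their median was 0.34 (adjusted p = 0.546 with an estimated correlation). Of 75 ribosome biogenesis genes, 2 rose and 44 fell (2 and 45 adjusted over the list alone). Their median was -0.40 (adjusted p = 0.48 with an estimated correlation). Examples are RPS17A (0.99), RPS7A (0.96), UTP8 (-0.86) and NOP16 (-1.03). Over all genes 961 rose and 1035 fell (1996, and 1132 in the joint fit of both assays). These libraries had a slope on coding length of -0.145 ± 0.105 (SD, n = 6) against 0.052 ± 0.070 in the pseudo-wild-type, and 5 genes were called with the library slopes, 3 of them shared. Between the forms edgeR called 0 genes (583 at an unadjusted p under 0.05, 137 by DESeq2, 482 without H3X replicate 4 and 2 without H3Y replicate 4), and between H3X and H3Y 0 (121, and 0 by DESeq2).

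R2 is methylated at the tip of the H3 tail, and K36 is methylated in transcribed genes. In symmetric R2K edgeR called 0 genes (788 at an unadjusted p under 0.05, 14 by DESeq2). Of 48 respiratory genes, 0 rose and 0 fell (9 and 0 adjusted over the list alone). Their median was 0.18 (adjusted p = 0.347 with an estimated correlation). NDI1 (0.40), SDH2 (0.47) and CYC1 (0.56) had the smallest p among them. GTT1, a glutathione transferase gene of the stress list (YIR038C, chromosome IX, 423809 to 424513), was at 171 ± 14.7 against 127 ± 9.51 CPM without passing (log2 fold change 0.43 ± 0.09, edgeR adjusted p = 0.0729). In symmetric against asymmetric R2K, edgeR called 0 (720, and 43 by DESeq2), and of 59 stress-induced genes 27 were higher adjusted over the list alone (median 0.35, adjusted p = 0.466 with an estimated correlation). R2K on 1 copy gave 0 (252, and 0 by DESeq2) and H3X against H3Y 0 (50, and 0 by DESeq2). Leaving out R2K double replicate 3 gave 29 genes for the symmetric strain and 72 between the forms, where H3X replicate 3 gave 40 and H3Y replicate 4 gave 7. In symmetric K36Q edgeR also called 0 (484, and 0 by DESeq2), but 48 without pseudo-wild-type replicate 8, 39 without K36Q double replicate 3 and 222 in the joint fit of both assays. Stress-induced genes leaned up, with 55 of 59 above 0 (median 0.32, adjusted p = 0.347 with an estimated correlation), for example DDR2 (0.68) and SSA4 (0.60). Ribosomal protein genes leaned down, with 130 of 131 below 0 (median -0.22, adjusted p = 0.389 with an estimated correlation), and the mating genes BAR1 (-0.50) and AGA2 (-0.62) were lower without passing over all genes. K36Q on 1 copy gave 0 (102, and 0 by DESeq2), the forms against each other 0 (657, and 2 by DESeq2, 107 without double replicate 3), and H3X against H3Y 0 (79, and 0 by DESeq2). In simulated data of the R2K design, edgeR recovered 79.1% of 1.5-fold changes and 100% of 2-fold changes between the symmetric strain and the pseudo-wild-type. Those data lacked the trend on coding length between libraries, so they cannot show that the counts of 0 mean no change.

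**Figure D4:**
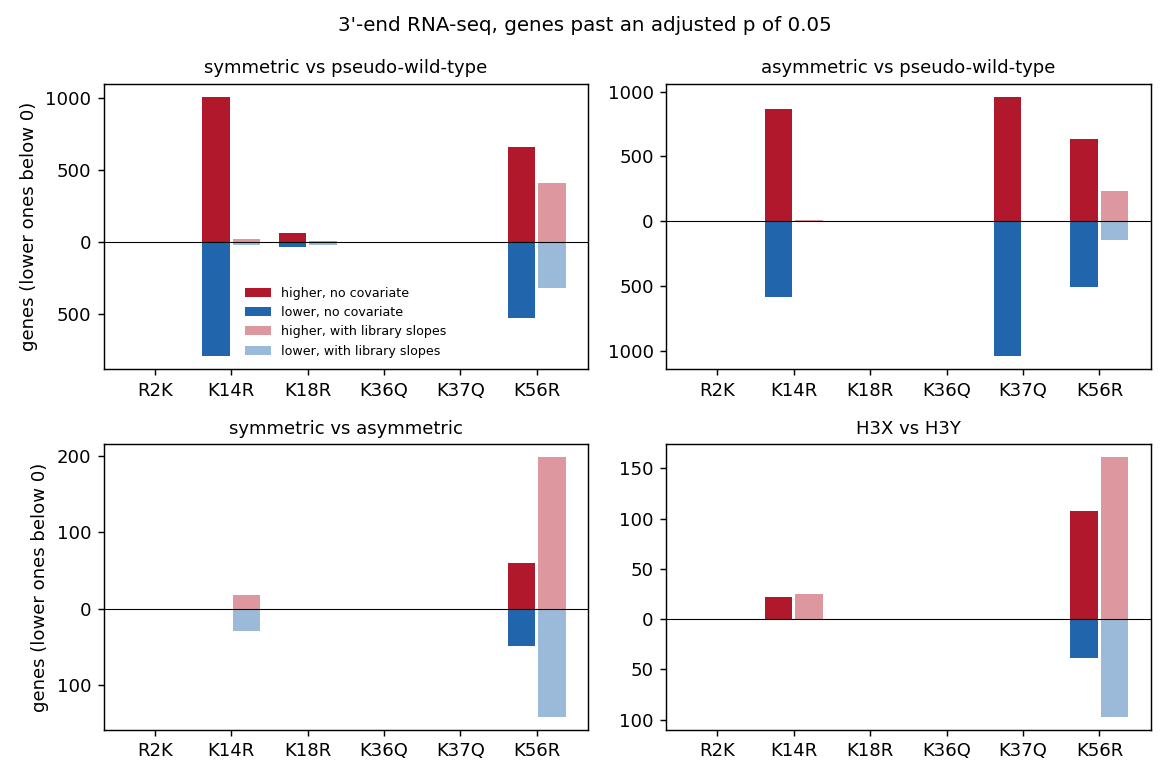
Number of genes past an adjusted p of 0.05 in each 3′-end comparison, higher above 0 and lower below 0, without (dark) and with (light) the library slopes as covariates. For symmetric K56R the totals are 1190 and 729, and for symmetric K14R 1801 and 42.

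Plasmid genes were compared in every 3′-end contrast, since both H3 copies and both markers sit on plasmids. LEU2 fell in K14R with both copies changed (184 ± 18.1 against 327 ± 43.0 CPM, log2 fold change -0.83 ± 0.15, edgeR adjusted p = 0.000347) and with 1 copy changed (-0.46). In asymmetric K37Q both LEU2 (0.55) and TRP1 (0.65) rose, and in symmetric K37Q LEU2 stood at 0.74 without passing (edgeR adjusted p = 0.152). HHT2 fell in symmetric K14R (-0.39), and in symmetric K18R it rose. Among the chromosomal histone genes, HTA1 (0.67) and HTA2 (0.49) rose in asymmetric K37Q, and HTA2 (-0.47) and HTB2 (-0.28) fell in symmetric K14R. None of these changes in K14R and K37Q, of LEU2, TRP1, HHT2, HTA1, HTA2 and HTB2, passed with the library slopes, and in the joint fit of both assays HTB2 stood at 0.31.

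How much of the symmetric effect a single changed copy gives was measured on genes chosen in the full-length libraries, so that the choice and the measurement share no library. Over the 200 genes with the smallest p there, K56R moved the 3′-end levels by a mean of 0.44 on the log2 scale in the direction seen in the full-length libraries when symmetric and by 0.21 when asymmetric, a ratio of 0.48 ± 0.07 (delete-1-library jackknife standard error), or 0.47 ± 0.08 with symmetric replicates 3 and 4 summed. For K18R the ratio was 0.95 ± 0.38, and 0.54 ± 0.17 with the library slopes. R2K gave 0.036 ± 0.15. For K14R, K36Q and K37Q the symmetric mean did not exceed 2 standard errors, and no ratio is given. Across genes, which are not independent replicates, log2 fold changes of symmetric strains in the 3′-end and the full-length libraries correlated with Pearson's r of 0.48 for R2K, 0.035 for K36Q, 0.30 for K37Q, -0.54 for K14R, 0.14 for K18R and 0.33 for K56R. Of the 13 full-length symmetric mutants, only the K56R 3′-end profile had its highest r with its own mutant (the next was 0.09), while R2K and K37Q were closer to S10A (0.65 and 0.60). With the library slopes in both fits the values were 0.29, 0.35, 0.16, 0.26, 0.24 and 0.60, and each mutant but K14R, for which K14Q gave 0.27, ranked its own mutant first.

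The symmetric mutants K9R, K9Q, S10A, K14Q, K18Q, K27R and K27Q have full-length libraries alone, compared with the pseudo-wild-type with the sequencing batch as a term. In K14Q, FAR1, which arrests the cycle for mating (YJL157C, chromosome X, 123836 to 126328), was at 97.1 ± 3.21 CPM (SD, n = 2) against 216 ± 8.11 CPM (n = 3) (log2 fold change -1.14 ± 0.25, edgeR adjusted p = 0.044). HFM1 of meiotic recombination was at 13.4 ± 4.75 against 43.2 ± 10.6 CPM (log2 fold change -1.86 ± 0.41, edgeR adjusted p = 0.044). The K14Q total was 6, the others being 4 short reading frames within the ribosomal DNA, YLR154W-B, YLR156C-A, YLR157C-C and YLR159C-A, with fold changes above 6 on the log2 scale, named after their values were seen. Because pseudo-wild-type replicates 1, 2 and 3 are so alike, the FAR1 and HFM1 calls are weakly founded: with these summed as 1 library the K14Q count was 0. It was also 0 without K14Q double replicate 2 or pseudo-wild-type replicates 1 or 2, and 3 without replicate 3. Mating genes leaned down in K14Q (25 of 36 below 0, 5 of 36 adjusted over the list alone; median -0.35; adjusted p = 0.0948 with an estimated correlation). DESeq2 called 2 genes in K14Q. S10A gave 2 genes by edgeR and 1031 by DESeq2, and the former are RPB8, a subunit shared by the RNA polymerases (1.27), and YNL108C (1.14), named after its values were seen. edgeR called 0 genes in K9R, K9Q, K18Q, K27R and K27Q. At an unadjusted p under 0.05 these had 117, 127, 457, 294 and 355, and DESeq2 called 0, 1, 3, 0 and 0. Ty elements leaned up in K9R (44 of 46 above 0, median 0.76, adjusted p = 0.771 with an estimated correlation) with reads that map uniquely among near-identical copies. In S10A they leaned down (38 adjusted over the list alone, median -1.05, adjusted p = 0.771 with an estimated correlation). Ribosomal protein genes in S10A leaned up (83 adjusted over the list alone, median 0.85, adjusted p = 0.771 with an estimated correlation), and 0 passed with the library slopes. The S10A count was 1897 without S10A double replicate 1 and 0 without double replicate 2, and with pseudo-wild-type replicates 1, 2 and 3 summed as 1 library it was 0. In simulated data of the K9R comparison, the only full-length design simulated, 22.4% of 2-fold and 65.2% of 3-fold changes were recovered. The simulated spread took in differences between strains and batches, so these shares are likely too low.

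The asymmetric full-length comparisons include 5 of the 8 mutants with no symmetric strain, K79A, K4R, K36R, T45A and delta4-20, the last lacking part of the H3 tail. In delta4-20 (1 library per strain) the mRNA decay gene TIS11 (YLR136C, chromosome XII, 415801 to 416658) was at 64.7 ± 15.1 against 29.6 ± 12.0 CPM (log2 fold change 1.74 ± 0.34, edgeR adjusted p = 0.0207). PUT1 (1.22) and CSM1 of chromosome pairing (1.74) rose, and the membrane protein degradation gene ASI1 fell (-1.49), among 6 rises and 1 fall. CSM1 lies in a part of chromosome III that stood at a median log2 ratio of 0.98 in the delta4-20 H3Y library. In S10A the translocon gene SSS1 (1.32) and the ribosomal protein genes RPL31B (1.18) and RPL24A (1.16) rose, among 6 genes. Ribosomal protein genes leaned up there (107 adjusted over the list alone, median 0.77, adjusted p = 0.598 with an estimated correlation), as they did in K36R (28, median 0.74, adjusted p = 0.699 with an estimated correlation). K9R gave 5 genes, YLR154W-B, YLR156C-A, YLR157C-C, YLR159C-A and YLR162W, and K14Q gave 3, YLR156C-A, YLR157C-C and YLR159C-A. K9Q and K18Q gave 1 each, YBR191W-A in both, and these were all named after their values were seen. edgeR called 0 genes in K27R, K27Q, K79A, K4R, K36R and T45A. At an unadjusted p under 0.05 there were 176, 241, 192, 119, 985 and 270, and DESeq2 called 0, 1, 0, 0, 3 and 0. By DESeq2 delta4-20 had 21 genes, S10A 123, and K9R, K14Q, K9Q and K18Q 0. The S10A count by edgeR was 87 without pseudo-wild-type replicate 4 and 83 without H3Y replicate 2, and that of delta4-20 ran from 0 to 17. With pseudo-wild-type replicates 1, 2 and 3 summed the counts of delta4-20, S10A, K9R, K9Q and K14Q were all 0. That of delta4-20 was also 0 without replicate 3, its batch's only control, so why calls were lost is open.

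Arginine and glutamine at the same lysine, which keep and remove its charge, were compared in symmetric full-length strains. For K14, the hexokinase gene GLK1 (YCL040W, chromosome III, 50838 to 52340) was at 1853 ± 1627 against 415 ± 18.3 CPM in arginine against glutamine (log2 fold change 2.20 ± 0.57, edgeR adjusted p = 0.0235). SOL4 of the pentose phosphate pathway (2.07), the enolase gene ENO1 (2.05), the linker histone gene HHO1 (1.38) and HTZ1 (1.00) were higher, and PAC2 (-1.93), IPK1 (-1.83) and the Mediator gene SRB4 (-1.77) lower. Of 46 Ty features 42 were lower (44 adjusted over the list alone; median -2.08; adjusted p = 0.886 with an estimated correlation). The total was 471 higher and 95 lower (566), but 0 without K14R double replicate 2 or K14Q double replicate 2, 57 without K14Q double replicate 1, 3191 without K14R double replicate 1, and 0 with the library slopes. With pseudo-wild-type replicates 1, 2 and 3 summed it was 177, by DESeq2 923, and in the joint fit 0. K18 gave 2 genes, YFL065C and YLR076C, named after their values were seen, and 0 with those replicates summed, with 1 by DESeq2. K9 and K27 gave 0 by edgeR (103 and 96 at an unadjusted p under 0.05, 1 and 0 by DESeq2). Batch 9 held K4A, K4Q and K56Q as asymmetric strains with 1 library each and no pseudo-wild-type. K4A against K4Q gave 0 by edgeR (162 at an unadjusted p under 0.05, 0 by DESeq2), and K56Q against both gave 1 (2 by DESeq2), YGR259C (log2 fold change 2.28), named after its values were seen. The edgeR p-values given here measure the spread between samples, part of which may be technical. In the full-length fits that spread takes in pseudo-wild-type replicates 1, 2 and 3 as separate libraries. The p-values of Fisher's exact test count genes and measure no spread between samples.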

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

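The tests on chromosomes III and XI, those of the K56R glucose-repressed genes against the length trend and against chromosome III, and the fits with library slopes were chosen only after the result was seen. Among the 3′-end pseudo-wild-type libraries of batch 10, DDR2 stood at 294.6 CPM in replicate 8, far above the 130.4 to 180.4 of the others. In batch 11 replicate 16 stood apart for 6 genes. These were MLP2 at 74.96 CPM (others 20.3 to 38.6), PNC1 at 643 (788 to 857) and POL4 at 15.6 (5.61 to 8.39), as well as RPS2 at 5336 (5928 to 6247), SET3 at 68.2 (22.8 to 28.5) and YOX1 at 44.6 (59.8 to 68.0). Replicate 17 had VPS51 at 4.00 CPM, below the 10.3 to 11.2 of the others. Each exceeded Dixon's limit for a single far value, which chance passes in about 1 of 20 groups, and 8 of 139 groups passed it. Replicate 16 was also the pseudo-wild-type library of its batch with the highest slope on coding length, 0.027.

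Symmetric mutants of the same batch were set against each other with the same controls, and genes passed in each of 6 pairs. The counts were 224 for R2K against K36Q, 5 for R2K against K37Q, 4 for K36Q against K37Q, 1707 for K14R against K18R, 406 for K14R against K56R and 1329 for K18R against K56R. With the library slopes in the fit the counts were 1, 188, 0, 50, 568 and 583, with 0, 5, 0, 32, 318 and 380 genes shared.

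In full-length libraries of strains whose called genes are reported from the 3′-end data alone, chromosome segments stood above the level in other strains. The medians of the log2 ratio were 1.03 and 0.99 for the chromosome XI segment in K14R H3X replicates 1 and 2, 0.85 and 0.91 for chromosome III in K56R H3X replicates 1 and 2, and 0.89 for chromosome I, 24000 to 226863, in K36Q H3X replicate 2. K56R double replicate 2, which enters the ratio, the comparison of assays and the full-length K56R median below, had 0.71 on chromosome X, 466 to 531366, and 0.64 on chromosome XV, 6175 to 111886. The other K36Q H3X libraries lay near 0 on chromosome I. In K56R double replicate 1 the chromosome X interval stood at -0.030.

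The first pattern is the trend of long, A-rich genes against short ones. Across genes, the log2 fold change followed the gene's slope on the same trend among pseudo-wild-type libraries of the other batch, with Spearman's rho of 0.643 in symmetric K14R, -0.744 in asymmetric K37Q and 0.647 in symmetric K56R. Of the mutant libraries, 2, 4 and 3 had totals inside the pseudo-wild-type range. For K56R that is every library, which argues against depth there. Partial overlap in K14R and K37Q cannot exclude it. In asymmetric K37Q the library with the fewest counts (H3X replicate 3, 1273107) also had the lowest slope, -0.287. Unequal RNA quality, library quality or depth may thus carry much of the K14R and K37Q counts. In K56R 467 of 1190 calls held with the library slopes, so quality may carry part. An effect of the substitution on long genes stays open, since mutant and trend go together in the 3′-end batches.

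The second pattern is the raised chromosomes of the H3X strains. A single batch or assay is argued against by the lower of the full-length libraries, at 0.85 for chromosome III in K56R and 0.99 for chromosome XI in K14R. The substitution itself is argued against by the H3Y and symmetric 3′-end libraries, whose values farthest from 0 were -0.068 and 0.056, and by the full-length ones, all below 0 and as low as -0.14 and -0.28. An extra copy of chromosome III and of the chromosome XI segment may be the source, since at least 97.7% and 100% of their genes lay above 0 in each H3X library, at about the log2 ratio of a doubling. This was found and tested on the same data, and DNA content was not measured.

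The third pattern is the rise of glucose-repressed genes in symmetric K56R. The length trend as the whole cause is argued against by an adjusted p = 0.000404 with an estimated correlation once the library slopes are in the fit. A cause limited to the 3′-end libraries is argued against by a median log2 fold change of 0.55 in full-length K56R (26 of 34 members above 0). The extra chromosome III is argued against by its level in the symmetric libraries, no farther from 0 than -0.068 in the 3′-end and at -0.14 and -0.12 in the full-length ones, all below 0. An effect of K56R on these genes may be the explanation, as a hypothesis. A difference in growth stage at harvest or in the strain, whose chromosome X stands higher, stays open and was not tested.

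Other splits of the same libraries into groups of the same sizes were counted, each entry giving the real count, the splits with a count as large and the highest other count. The H3X and H3Y libraries were pooled as 1 group in these fits, so real counts can differ from those reported. Shares of splits were not corrected over comparisons, so none excludes chance. The share was under 0.05 for symmetric K14R (1801 genes, 1 of 84, highest other 1083) and K56R (1190, 1 of 84, highest other 566). It was larger for symmetric K37Q (6, 6 of 84, highest other 305) and K18R (94, 14 of 84, highest other 732). For asymmetric strains it was under 0.05 for K37Q (2004, 1 of 100, highest other 1374) and K14R (1438, 1 of 100, highest other 713). It was so too for K56R, asymmetric (1096, 1 of 100, highest other 674) and between the forms (59, 2 of 84, highest other 166). The near-identical symmetric K56R libraries were split as separate ones. For H3X against H3Y the 10 splits are too few for a share under 0.05: K14R (23 genes, 1 of 10, highest other 0) and K56R (147 genes, 1 of 10, highest other 0). In K56R the other splits that part all 3 same-number pairs gave 0 like the rest. Where the real count is 0, every split gives as many and the splits decide nothing. The highest other counts there were R2K 20 and K36Q 778 for symmetric strains, R2K 55, K36Q 3 and K18R 789 for asymmetric strains, R2K 129, K36Q 22, K37Q 1245, K14R 29 and K18R 1368 between the forms, and R2K 3, K36Q 0, K37Q 172 and K18R 0 for H3X against H3Y. Splits that call many more genes than the real one point to a structure of the samples, as in K36Q, K37Q and K18R. The highest other K56R and K14R splits of symmetric strains set pseudo-wild-type replicates 17, 18 and 19 apart, and those between the forms set the H3X libraries, with their raised chromosomes, against the rest.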

How the results depend on the processing

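The fits with library slopes, those without the shallowest libraries, the libraries of largest spread or segment genes, those with pseudo-wild-type replicates 1, 2 and 3 or K56R double replicates 3 and 4 summed and that with slopes and block were chosen only after the result was seen. Of the named genes, 172 of 173 kept their direction and their side of the threshold under DESeq2, 171 of 177 with RLE size factors and 174 of 177 without a filter. The numbers were 141 of 142 without segment genes, 135 of 161 with the mutant and pseudo-wild-type alone, 88 of 174 in the joint fit, 102 of 177 with the library slopes and 126 of 133 with K56R double replicates 3 and 4 summed, where VPH2, NAT5, HTZ1, APS3, SPC72, DPA10 and BET3 were lost. Among counts and other values, 26 of 49 held under DESeq2, 46 of 49 with RLE size factors, 47 of 49 without a filter, 25 of 47 in the joint fit and 33 of 65 with the library slopes. The K56R ratio of 0.48 stayed between 0.44 and 0.54 with any mutant library left out, and at 0.47, 0.44, 0.49, 0.50 and 0.52 with 100 genes, with 500 genes, with split controls, with the slopes and without segment genes, and at 0.47 with K56R double replicates 3 and 4 summed. In what follows the reported value stands in parentheses, and where no reason is given the cause was not tested.

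With DESeq2, the 3′-end counts that changed were R2K symmetric 14 (0), R2K between forms 43 (0), K36Q between forms 2 (0), K37Q between forms 137 (0), K14R between forms 21 (2), K18R symmetric 244 (94) and K18R between forms 110 (0). The full-length counts that changed were K9Q symmetric 1 (0), S10A symmetric 1031 (2), K14Q symmetric 2 (6), K18Q symmetric 3 (0), K9R asymmetric 0 (5), K9Q asymmetric 0 (1), S10A asymmetric 123 (6) and K14Q asymmetric 0 (3). K18Q asymmetric 0 (1), K27Q asymmetric 1 (0), K36R asymmetric 3 (0), delta4-20 asymmetric 21 (7), K9R against K9Q 1 (0), K14R against K14Q 923 (566), K18R against K18Q 1 (2) and K56Q against K4A and K4Q 2 (1) likewise changed. With RLE size factors, the full-length counts that changed were S10A symmetric 1 (2), S10A asymmetric 0 (6) and delta4-20 asymmetric 3 (7). With no filter on low counts, the full-length counts that changed were S10A symmetric 1 (2) and delta4-20 asymmetric 4 (7).

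In the joint fit of both assays, the 3′-end counts that changed were K36Q symmetric 222 (0), K36Q between forms 232 (0), K37Q asymmetric 1132 (1996), K14R symmetric 358 (1801) and K14R asymmetric 18 (1448). K14R between forms 266 (2), K18R symmetric 40 (94), K56R symmetric 506 (1190) and K56R asymmetric 213 (1141) likewise changed. The full-length counts that changed were S10A symmetric 35 (2), K14Q symmetric 2 (6), K18Q symmetric 1 (0), K27Q symmetric 1 (0), K9R asymmetric 0 (5), K9Q asymmetric 2 (1) and K14Q asymmetric 0 (3). K18Q asymmetric 0 (1), K4R asymmetric 2 (0), delta4-20 asymmetric 13 (7), K14R against K14Q 0 (566), K18R against K18Q 1 (2) and K27R against K27Q 1 (0) likewise changed. Of the other values, HTB2 in K14R symmetric 0.31 (-0.28) and PRY2 in K14R between forms 0.019 (-0.54) changed. With only the mutant and the pseudo-wild-type in the fit, the 3′-end counts that changed were K37Q symmetric 0 (6) and K18R symmetric 0 (94). With the replicate number as a block, K14R between forms gave 0 (2), where the libraries share only a number. In K56R H3X against H3Y, where libraries with the same number correlated, the block gave 126 (147), 123 of them shared. With the block and the library slopes it gave 233 (147), of which 145 are shared, and 258 with the slopes alone. The block changed no call of a named gene there, and 0 lists passed with an estimated correlation.

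With the library slopes as covariates, the 3′-end counts that changed were K37Q symmetric 0 (6), K37Q asymmetric 5 (1996), K14R symmetric 42 (1801), K14R asymmetric 9 (1448) and K14R between forms 47 (2). K18R symmetric 26 (94), K56R symmetric 729 (1190), K56R asymmetric 370 (1141), K56R between forms 339 (109) and K56R H3X against H3Y 258 (147) likewise changed. The full-length counts that changed were K9Q symmetric 8 (0), S10A symmetric 0 (2), K14Q symmetric 19 (6), K9Q asymmetric 36 (1), S10A asymmetric 0 (6) and K14Q asymmetric 0 (3). K18Q asymmetric 3 (1), K27R asymmetric 3 (0), T45A asymmetric 3 (0), delta4-20 asymmetric 55 (7), K14R against K14Q 0 (566) and K56Q against K4A and K4Q 11 (1) likewise changed. Of the other values, K18R ratio 0.54 (0.95), R2K r between assays 0.29 (0.48), K36Q r between assays 0.35 (0.035), K37Q r between assays 0.16 (0.30), K14R r between assays 0.26 (-0.54), K18R r between assays 0.24 (0.14), K56R r between assays 0.60 (0.33), MLP1 in K14R symmetric -0.059 (2.02), UTP14 in K14R symmetric -0.12 (1.75) and MLP1 in K14R asymmetric -0.041 (1.60) changed. The lists passing with the preset correlation went to 14 (24) of 150 for H3X against H3Y, 12 (34) of 120 for arginine against glutamine and 36 (69) of 210 for full-length symmetric strains. With an estimated correlation 0 lists passed in the 3′-end asymmetric (53), H3X against H3Y (24), between-form (44) and symmetric (57) families and in the full-length arginine against glutamine (34), asymmetric (101), batch 9 (17) and symmetric (69) families. With the slopes and an estimated correlation 1 list passed in the 3′-end asymmetric, 1 in the 3′-end symmetric and 1 in the full-length symmetric family, and 0 in the other 5.

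Without the shallowest library of each 3′-end batch, the 3′-end counts that changed were R2K between forms 3 (0), K14R between forms 8 (2) and K18R symmetric 0 (94). Of the other values, RPS31 in K18R symmetric -0.068 (1.82) and RPL23B in K18R symmetric -0.058 (1.82) changed. Without genes in raised chromosome segments, with p adjusted anew over the others, the 3′-end counts that changed were K14R between forms 0 (2), K14R H3X against H3Y 1 (23), K56R between forms 25 (109) and K56R H3X against H3Y 13 (147). Outside the segments K56R between forms had 42 calls and K56R H3X against H3Y 43 before that adjustment, so that both the lost genes and the new adjustment of unchanged p-values lower these counts. Without the libraries of largest spread, the full-length counts that changed were S10A symmetric 0 (2), K27Q symmetric 1 (0), K9Q asymmetric 2 (1), S10A asymmetric 16 (6), K36R asymmetric 1 (0), delta4-20 asymmetric 51 (7) and K14R against K14Q 0 (566). With pseudo-wild-type replicates 1, 2 and 3 summed, the full-length counts that changed were S10A symmetric 0 (2), K14Q symmetric 0 (6), K9R asymmetric 0 (5), K9Q asymmetric 0 (1) and S10A asymmetric 0 (6). K14Q asymmetric 0 (3), delta4-20 asymmetric 0 (7), K14R against K14Q 177 (566) and K18R against K18Q 0 (2) likewise changed. With K56R double replicates 3 and 4 summed, the 3′-end counts that changed were K56R symmetric 744 (1190) and K56R between forms 47 (109). With that sum and the library slopes, the 3′-end counts that changed were K14R symmetric 41 (1801), K14R asymmetric 8 (1448), K14R between forms 43 (2), K18R symmetric 26 (94), K56R symmetric 613 (1190), K56R asymmetric 355 (1141), K56R between forms 214 (109) and K56R H3X against H3Y 244 (147). Of the other values, MLP1 in K14R symmetric -0.057 (2.02), UTP14 in K14R symmetric -0.11 (1.75) and MLP1 in K14R asymmetric -0.045 (1.60) changed. With genes of at least 20 CPM in both assays alone, K36Q r between assays -0.057 (0.035), K14R r between assays -0.60 (-0.54) and K18R r between assays 0.19 (0.14) changed.

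Leaving out each library in turn moved these 3′-end counts by more than 1.5 times, given as the range with each library that did so (double is the symmetric strain and pWT the pseudo-wild-type, with the replicate number): R2K symmetric 0 to 29 (29 without double 3). R2K between forms 0 to 72 (40 without H3X 3, 7 without H3Y 4, 72 without double 3). K36Q symmetric 0 to 48 (48 without pWT 8, 39 without double 3). K36Q between forms 0 to 107 (107 without double 3). K37Q symmetric 0 to 104 (1 without double 5, pWT 8, 3 without pWT 9, 104 without pWT 10, 0 without double 4, pWT 11/12/13). K37Q between forms 0 to 482 (482 without H3X 4, 2 without H3Y 4). K14R symmetric 1115 to 2131 (1115 without double 5). K14R asymmetric 909 to 1912 (909 without H3X 3). K14R between forms 0 to 4 (4 without H3X 3, 1 without H3X 4, H3Y 4, H3Y 5, 0 without H3X 5, double 3, double 4, double 5). K18R symmetric 0 to 588 (54 without pWT 14, 43 without pWT 15, 588 without double 4, 0 without double 5, 46 without pWT 18, 40 without pWT 19). K18R asymmetric 0 to 9 (9 without pWT 16). K18R between forms 0 to 531 (120 without H3Y 4, 86 without double 3, 531 without double 4). K56R symmetric 546 to 1626 (733 without double 3, 714 without double 4, 546 without double 5). K56R asymmetric 696 to 1701 (736 without H3X 3, 696 without H3Y 3, 703 without H3Y 4). K56R between forms 38 to 127 (49 without double 3, 43 without double 4, 38 without double 5).

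For the full-length counts the same ranges were S10A symmetric 0 to 1897 (0 without double 2, pWT 1/3/5, 1 without pWT 2, 1897 without double 1). K14Q symmetric 0 to 5 (0 without double 2, pWT 1/2, 3 without pWT 3). K18Q symmetric 0 to 1 (1 without double 1). K27Q symmetric 0 to 4 (1 without double 1, 4 without double 2). K9R asymmetric 0 to 5 (0 without H3X 2, H3Y 2, pWT 1). K9Q asymmetric 0 to 2 (2 without pWT 2, 0 without pWT 3/4). S10A asymmetric 0 to 87 (83 without H3Y 2, 0 without H3X 1, H3Y 1, pWT 2/3/5, 1 without H3X 2, 87 without pWT 4). K14Q asymmetric 0 to 3 (0 without H3X 2, H3Y 2, pWT 1/2). K18Q asymmetric 0 to 1 (0 without H3X 2, H3Y 2, pWT 4). K79A asymmetric 0 to 1 (1 without H3Y 2). delta4-20 asymmetric 0 to 17 (2 without pWT 2, 0 without pWT 3, 17 without pWT 4, 12 without pWT 5). K14R against K14Q 0 to 3191 (57 without K14Q double 1, 3191 without double 1, 0 without double 2, K14Q double 2). K18R against K18Q 0 to 1 (0 without double 1, K18Q double 2, K18Q double 1, 1 without double 2). K27R against K27Q 0 to 1 (1 without K27Q double 1). In these fits a strain left with 1 library is assumed to vary like the other strains.

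Depth and library number set what is detectable. With the 2 libraries of symmetric K9R, the only full-length comparison simulated, 22.4% of 2-fold changes were recovered, so a count of 0 there is weak evidence. Comparisons of strains with 1 library were not simulated, while the 3′-end comparisons of R2K with the pseudo-wild-type recovered 100% and H3X against H3Y 98.5%.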

Other observations

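All values in this part come from fits with the library slopes or from lists and genes chosen only after the result was seen, and none was tested further. With the slopes in the fit, 6 of 22 mating genes fell and 0 rose in symmetric K14R (adjusted p = 0.136 with an estimated correlation). SST2, which desensitises the pheromone pathway, had a log2 fold change of -0.95 ± 0.18, the pheromone protease gene BAR1 -0.75 ± 0.16 and AGA2 -0.84 ± 0.21. Of nitrogen genes, the glutamate dehydrogenase genes GDH1 (-0.73 ± 0.11) and GDH2 (-0.78 ± 0.14) were lower and the ammonium transporter gene ATO2 was higher (1.08 ± 0.19). HFM1 was lower in symmetric K14R (-1.33 ± 0.26) and in full-length symmetric K14Q (-1.91 ± 0.28), as was the peroxidase gene GPX2 (-0.74 ± 0.12 and -1.32 ± 0.29), so that for these genes both substitutions of K14 went the same way. Without the slopes SST2, GDH2 and HFM1 did not pass in K14R and stood at 0.058, 0.12 and -0.23 (edgeR adjusted p = 0.865, 0.711 and 0.580), and GPX2 did not pass in K14Q (-0.63, edgeR adjusted p = 0.924).

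The iron retention genes FIT3 and FIT2 were higher in symmetric K14R, by log2 fold changes of 1.36 ± 0.16 (edgeR adjusted p = 5.52e-07) and 1.01 ± 0.18. Of 28 iron regulon genes 2 rose and 0 fell there (adjusted p = 0.172 with an estimated correlation). FIT3 also stood above the asymmetric K14R strains (0.69 ± 0.11), as did ADA2 of the SAGA complex (1.07 ± 0.23) and ATO2 (0.60 ± 0.12), but without the slopes these did not pass (edgeR adjusted p = 0.0924, 0.210 and 0.433). In K56R H3X against H3Y the mating genes MFA1 (-1.12 ± 0.21), STE2 (-0.76 ± 0.13), BAR1 (-0.71 ± 0.13), MFA2 (-0.67 ± 0.12) and SST2 (-0.66 ± 0.15) were lower, of which SST2 did not pass without the slopes (-0.44, edgeR adjusted p = 0.629). Chromosome III, which carries the mating-type locus and both silent copies, stood higher in that H3X strain.

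Chromosome segments at a raised level were also found in K56Q H3Y, on chromosome XVI from 810984 to 844020 at a median log2 ratio of 0.88, and in delta4-20 H3Y, on chromosome III from 201174 to 314981 at 0.98. In all 15 segments were found in 14 libraries.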
